A study of Mus musculus castaneus and Mus musculus domesticus and Mus musculus with 11 samples.

How the data were processed

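RNA sequencing of motor neurons differentiated from mouse embryonic stem cells was analysed for 9 libraries, 3 from each of 3 lines. The lines were 129S6/SvEv, a laboratory strain background called 129 here, CAST/EiJ, a wild-derived strain called CAST here, and a CASTx129 cross called the hybrid here. The labels list 11 samples, and 2 further CAST samples, numbered 7 and 8, belong to another read matrix and were not analysed here. Per the labels, total RNA was purified with a column kit and treated with DNase, polyadenylated RNA was selected, and cDNA was primed with random hexamers. Per the submitters' processing notes, reads were aligned with STAR to mm10. The STAR version, the counting tool, the gene annotation behind the counts and the strand setting are not given in the sources used here.

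The deposited matrix holds counts, that is, whole numbers of reads for each of 27071 Ensembl genes in each of the 9 libraries, and the authors applied no normalization that the values show. Column names give the line and a number after the letter B, which was taken as the replicate number of the labels, and every per-sample column was used. Whether an equal B number marks a shared differentiation batch is not stated, and with it as a block 6 of the 136 calls in CAST against 129 were left. Symbols were joined by Ensembl gene ID from a GENCODE annotation of GRCm38, the assembly also called mm10. A symbol was found for 27030 IDs and none for 41. Coordinates, exon lengths and exon overlaps come from that annotation, which need not be the one used for counting. Total counts ran from 7763077 to 18167577, and 5648 genes had 0 counts in all libraries. The labels do not say whether the 3 libraries of a line came from separate cultures, so p-values measure only the spread between these samples.

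Genes were kept by filterByExpr of edgeR with the groups given (minimum count 10, minimum total count 15, minimum proportion 0.7), which left 14839. Counts were scaled by TMM and fitted with the robust quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with all 3 groups in 1 fit and no covariates. The comparisons were CAST against 129, hybrid against 129, hybrid against CAST, and hybrid against the midparent, the mean of both parental lines on the log2 scale (weight 0.5 each). A joint F test asked whether a gene differed among any of the 3 groups. P-values were two-sided and adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Fold changes are given as log2 values with the standard error (SE) from the quasi-likelihood F statistic. Expression levels are values of the cpm function of edgeR (CPM) after TMM scaling, as mean ± SD with n = 3. The replicate numbers were not used to pair libraries, since the labels give no pairing. After group means were removed, 2 of 9 same-number pairs had a correlation above 0.1 (range −0.72 to 0.49). With n = 3 these correlations cannot rule a pairing out.

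A group at 0 counts gives no fold, so its floor was set at 3 counts over the group and the fold is printed as a bound. Bounds and ratios compare counts summed over a group and divided by its summed scaled library sizes, so deeper libraries weigh more, and a bound can lie above or below the ratio of the printed mean CPM to the floor. With 1 to 3 counts, the ratio is printed with an exact 95% counting interval. Intervals and floors cover counting error only, since reads were not traced to single molecules.

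Sets of genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over lists within a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. The 38 lists hold 799 genes, of which 670 were tested, 66 were absent from the matrix and 1 had no symbol. They cover motor neuron and spinal cord identity, Hox genes, other cell types, axon growth, stress and metabolism. Chromosomes were tested as sets in the same way. The comparisons, lists, tests, alternative settings and the rule for named genes were written before the data were examined.

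The rule named, in each comparison, the largest changes in each direction (10 for CAST against 129, 5 for the others) among genes past the threshold with a mean of at least 5 CPM over the 9 libraries. Outside the midparent comparison it also asked that the libraries of the compared groups did not overlap. It left out predicted or unnamed genes, Y-linked genes and Xist. From each list it named up to 3 members in each direction past the threshold in CAST against 129, or, where none passed, the 2 with the highest mean CPM. It also named Mnx1, Isl1, Lhx3, Chat, Olig2, Pou5f1, Inhba, Gap43, Atf3 and Xist in every case. Pou5f1 did not pass the expression filter. Members of the lists that passed the threshold in a hybrid comparison lie outside this rule where they did not pass in CAST against 129, and they were chosen after their values were seen.

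The alternative settings fixed in this way were DESeq2 1.42.0, limma-voom, other scalings (RLE, upper quartile, none), a filter at 1 CPM in at least 3 libraries, no filter, a replicate block, a threshold of 0.01, a minimum absolute log2 fold change of 1, a fit without robust estimation, a fit of the 2 compared groups alone, and leaving out each library. Alternatives chosen after seeing the data left out the libraries CAST 1 and hybrid 2, added an exon length offset (lowess, span 0.5), left out genes at the floor in a group, left out genes whose exons overlap another gene, summed overlapping genes, and weighted libraries in limma-voom. The closing section gives their effect. An alternative that would have added the 2 further CAST samples was not run. Upper quartile scaling moved the median log2 fold change over all genes from 0.02 to 0.23 in hybrid against 129 and from −0.02 to 0.17 against the midparent, and from −0.08 to 0.09 in hybrid against CAST. Changes below are relative to the TMM scaling.

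The pipeline was tested on simulated counts with these depths and this spread (common biological coefficient of variation 0.516), over 14565 genes with known changes between CAST and 129. EdgeR called 0% of genes changed 2-fold, 18.8% of those changed 4-fold, 84% at 8-fold and 98.0% at 16-fold, with 4 false calls. DESeq2 called 6%, 52.1%, 88% and 100%, with 29 false calls. Limma-voom called 0%, 20.8%, 76% and 98.0%, with 7 false calls. At this spread and n = 3, changes under about 8-fold were therefore often missed by edgeR. The simulated counts were drawn once, with genes independent and their spread taken from the trend over expression level. They held no length slopes or other structure of the libraries, so their false calls do not measure those in the real counts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.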

Results

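Polyadenylated RNA was sequenced from motor neurons differentiated from embryonic stem cells of 3 mouse lines, 129, CAST and the hybrid of both, with 3 libraries per line. The stated purpose of the series was to compare the transcriptional identity of lines used to study variation in neurite growth. Total counts of replicates 1 to 3 were 18167577, 16763198 and 17179629 in 129, 14502335, 7763077 and 12362162 in the hybrid, and 11167254, 16374911 and 13555712 in CAST. Of 27071 genes, 14839 were tested. In a principal component analysis of the 500 most variable genes, the first component held 82.1% of the variance and set the hybrid libraries apart from both parental lines, and the second held 11.7% and parted 129 from CAST.

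**Figure D1:**
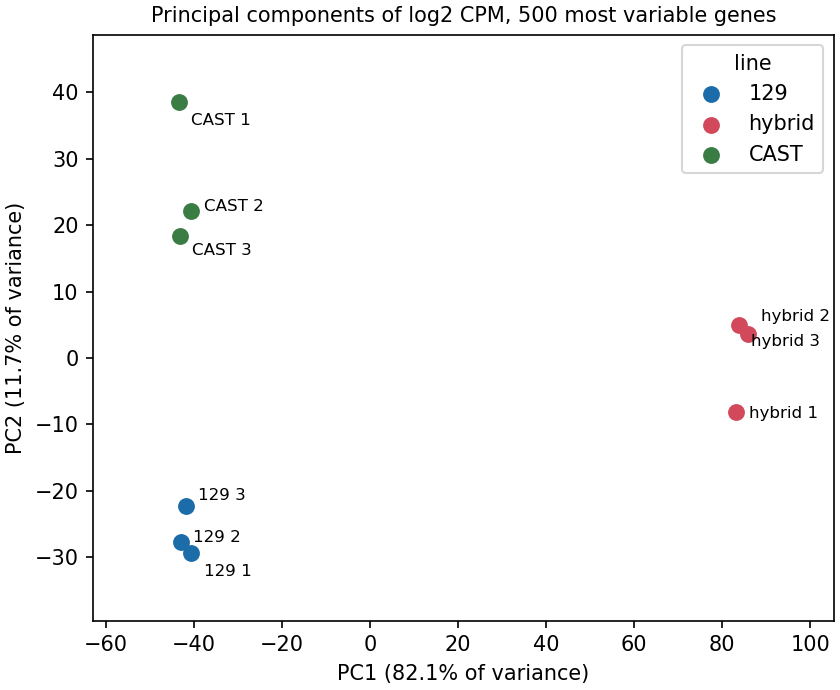
Scores of the 9 libraries on the first and second principal components of log2 CPM of the 500 most variable genes, with the percent of variance on each axis (82.1% and 11.7%); points are libraries, coloured by line. The hybrid libraries lie apart from both parental lines on the first axis, and 129 and CAST part on the second.

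The libraries CAST 1 and hybrid 2 stood apart from the rest in 1 respect. Short transcripts were relatively abundant and long transcripts scarce in both. Over 12507 genes, the slope of relative log2 expression on log2 exon length was −0.78 per doubling in CAST 1 and −0.67 in hybrid 2. It was −0.18 in hybrid 3 and between 0.17 and 0.35 in the other 6 libraries.

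**Figure D2:**
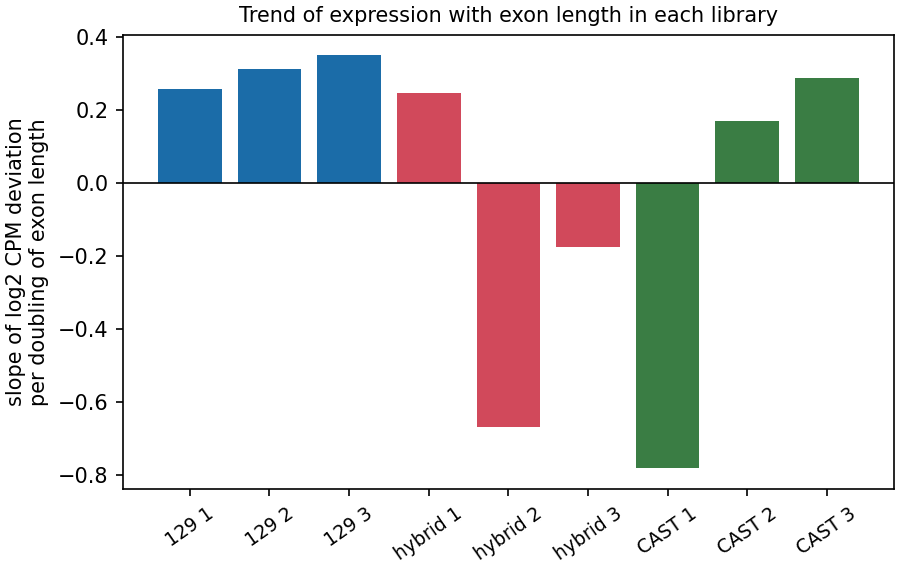
Slope of relative log2 expression per doubling of exon length in each of the 9 libraries, over 12507 genes; bars are libraries, coloured by line, and the axis includes 0. CAST 1 (−0.78) and hybrid 2 (−0.67) have the lowest slopes.

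The first comparison asked how the motor neuron cultures of the parental lines differ. Camera with a preset correlation called genes of the extracellular matrix and the posterior Hox genes, which pattern the trunk spinal cord, lower in CAST than in 129 (adjusted p = 5.5e-06 and 4.6e-05; adjusted p = 0.794 and 0.586 with an estimated correlation). EdgeR called 0 of 27 and 0 of 13 members of these lists (7 and 7 at an unadjusted p under 0.05, 2 and 4 by DESeq2). Of 3 tested mitochondrially encoded genes, mt-Nd5 and mt-Nd6 were called higher in CAST and mt-Cytb was at 0 counts in both lines. The complex I subunit mt-Nd5 was at 1308 ± 228 CPM in CAST and 113 ± 35.2 CPM in 129. Igf2, an imprinted growth factor, was at 20.4 ± 7.17 CPM in CAST and 1231 ± 600 CPM in 129, and Lmx1b, a transcription factor of dorsal interneurons and serotonergic neurons, at 17.8 ± 6.57 CPM and 2.01 ± 1.47 CPM (SD, n = 3 in each group). EdgeR called 136 genes, 58 higher and 78 lower in CAST, with 2164 at an unadjusted p under 0.05. The libraries of the 2 lines did not overlap in any of the 136, and in 28.6% of all tested genes, where chance gives 10%. DESeq2 called 939 and limma-voom 234. The count was 51, 26 and 32 without 129 1, 129 2 and 129 3, and 31 and 61 without CAST 2 and CAST 3.

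The posterior Hox list (paralogues 6 to 13) had a positive log2 fold change in 1 of 13 tested members, with a median of −2.04, also −2.04 with members at the floor set to their bound. Camera gave an adjusted p of 4.6e-05, and 0.586 with an estimated correlation. EdgeR called 0 of the 13 over all genes and 6 lower adjusted over the list alone (7 lower at an unadjusted p under 0.05, 4 called by DESeq2, 0 by limma-voom). The mean over the list was 3.26 log2 CPM in 129, 2.29 in the hybrid and 1.39 in CAST. The members with the most reads, Hoxb8 and Hoxb6, had log2 fold changes of −0.61 ± 0.48 and −0.34 ± 0.41 (SE) and did not pass. The anterior Hox genes (paralogues 1 to 5) of hindbrain and cervical cord had a positive value in 12 of 13 members, a median of 0.51 and a camera adjusted p of 0.0769.

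The extracellular matrix list was positive in 4 of 27 members, with a median log2 fold change of −1.66 (camera adjusted p = 5.5e-06; adjusted p = 0.794 with an estimated correlation). EdgeR called 0 of 27 over all genes and 1 lower adjusted over the list alone (7 lower at an unadjusted p under 0.05, 2 by DESeq2, 1 by limma-voom). Fn1, the adhesive glycoprotein fibronectin, stood at 3086 ± 2838 CPM in CAST and 11047 ± 6577 CPM in 129 (log2 fold change −1.84 ± 1.52, adjusted p = 0.556). The list mean was 7.16 ± 0.31 log2 CPM in 129 and 5.26 ± 1.79 in CAST (SD, n = 3), where CAST 1 was at 3.25, CAST 2 at 5.88 and CAST 3 at 6.66. Fibroblast and mesenchyme markers were positive in 3 of 17 members (median −1.91, camera adjusted p = 0.00151; adjusted p = 0.794 with an estimated correlation), with 5.46 log2 CPM in CAST 1. Without both CAST 1 and hybrid 2 the fibroblast adjusted p was 0.0747 and that of the extracellular matrix 0.0173. The fibroblast list mean was 9.004 log2 CPM in 129 and 6.994 in CAST. That of spinal motor neuron identity was lower, at 4.123 and 3.687. Differences in extracellular matrix and fibroblast genes therefore need not be differences between motor neurons. The share of each cell type was not tested. Oligodendrocyte lineage genes were positive in 0 of 12 members, with a median of −1.66, −1.39 at the bound and −0.38 without 129 1 (camera adjusted p = 0.00151; adjusted p = 0.505 with an estimated correlation). EdgeR called 0 of these 12 and 3 lower adjusted over the list alone (4 lower at an unadjusted p under 0.05, 4 by DESeq2, 2 by limma-voom).

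**Figure D3:**
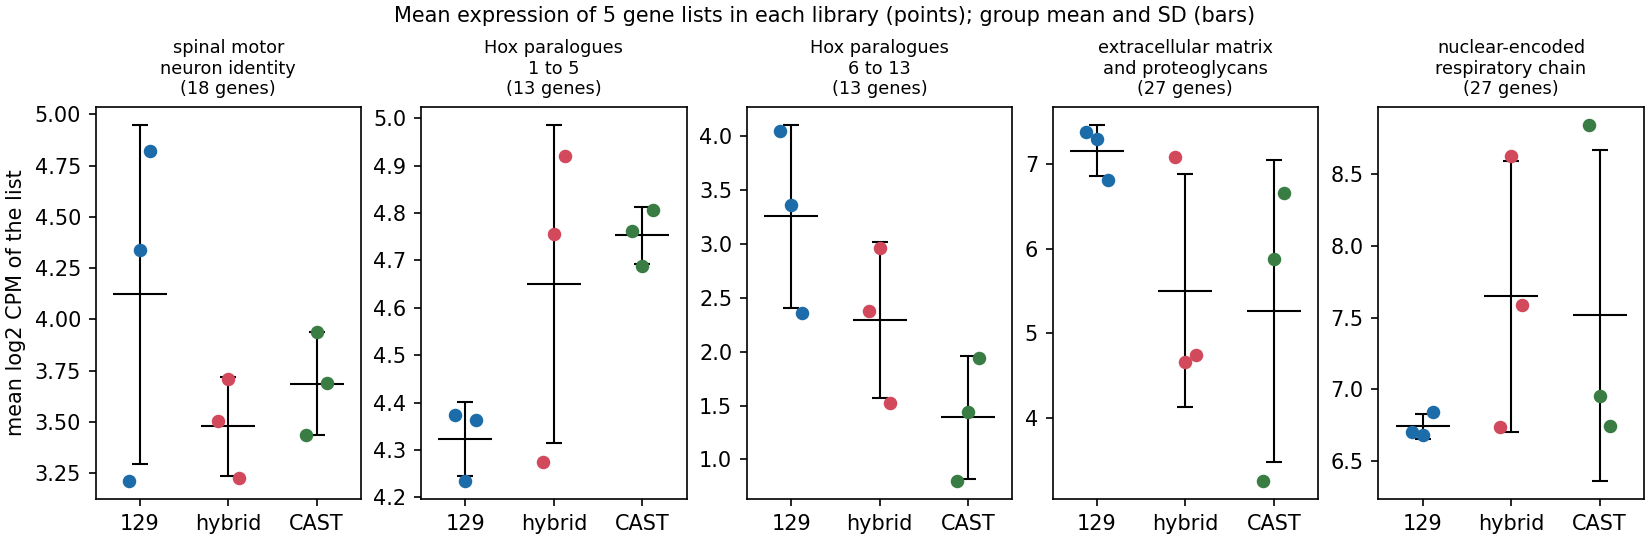
Mean log2 CPM over the tested members of 5 gene lists in each library; points are libraries, and bars give the mean and SD of the 3 libraries of each line. For extracellular matrix genes CAST 1 (3.25) lies below CAST 2 (5.88) and CAST 3 (6.66), and for posterior Hox genes the line means are 3.26 in 129, 2.29 in the hybrid and 1.39 in CAST.

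Both mitochondrial genes called in CAST encode complex I subunits. The log2 fold change of mt-Nd5 was 3.53 ± 0.49 (SE, edgeR adjusted p = 0.0274), and mt-Nd6 was at least 181-fold higher (9.51 ± 5.64 CPM against 0, adjusted p = 0.0434). The list of 3 tested members had a median of 3.53, a camera adjusted p of 0.00151 and a fry adjusted p of 1.17e-04 (camera adjusted p = 0.315 with an estimated correlation, and 0.0544 with the exon length offset). With mt-Cytb, at the floor in both lines, left out and mt-Nd6 set to its bound, the median was 5.51. The calls ended without 129 1, 129 2, 129 3, CAST 2 or CAST 3, with adjusted p of 0.139, 0.156, 0.138, 0.0856 and 0.0583 for mt-Nd5, and 0.127, 0.142, 0.128, 0.152 and 0.101 for mt-Nd6. Mitochondrial genes took 0.133%, 0.145% and 0.112% of counts in CAST 1 to 3, at most 0.0141% in 129 and at most 0.00925% in the hybrid. The matrix holds 13 of these genes, of which 3 were tested. How mitochondrial reads were counted is not known, so differences in these genes need not be differences in expression.

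Nuclear genes of the respiratory chain were positive in 27 of 27 members in CAST, with a median of 1.06 (camera adjusted p = 0.00335; adjusted p = 0.836 with an estimated correlation), while edgeR, DESeq2 and limma-voom called 0 (0 at an unadjusted p under 0.05). The list stood at 8.85 log2 CPM in CAST 1 and 6.96 and 6.74 in CAST 2 and CAST 3. Without CAST 1 the median was 0.07 and the adjusted p 0.785. Genes of activin and TGF-beta signalling (4 of 27 positive, median −0.64, camera adjusted p = 0.00663; adjusted p = 0.794 with an estimated correlation) also depended on CAST 1, without which the adjusted p was 0.143 and the median −0.40. Without CAST 3 their median was −1.13. Cell adhesion genes (5 of 29 positive, median −0.58, camera adjusted p = 0.0292; adjusted p = 0.836 with an estimated correlation) had an adjusted p of 0.929 and a median of −0.15 without CAST 1, and a median of −0.89 without CAST 3. Axon guidance genes (12 of 41 positive, median −0.45, camera adjusted p = 0.0415; adjusted p = 0.836 with an estimated correlation) had an adjusted p of 0.929 with a median of −0.01 without CAST 1, and 0.101 with a median of −0.19 without 129 3. The axon guidance median was −0.77 without CAST 3. With the exon length offset, chosen after seeing the data, the calls of cell adhesion and axon guidance genes ended (camera adjusted p = 0.373 and 0.530; over the alternatives from 0.00200 for each to 0.953 and 0.929). Without both CAST 1 and hybrid 2 the respiratory chain, TGF-beta, adhesion and axon guidance calls all ended (adjusted p = 0.669, 0.159, 0.953 and 0.873). EdgeR called 0 members of these 3 lists over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 1, 4 and 4, and DESeq2 called 0, 2 and 2. The means in CAST 1 were 3.74, 4.28 and 4.03 log2 CPM, against 5.01, 6.43 and 5.98 in CAST 2.

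A further 4 lists passed camera in CAST against 129, each with p above the threshold with an estimated correlation. Muscle genes (2 of 13 positive) had a median of −1.03 and an adjusted p of 0.0292, 0.794 with an estimated correlation. Their adjusted p was 0.0943, 0.105 and 0.102 without 129 1, CAST 2 and CAST 3, and their median −0.52, −0.69 and −2.07 without 129 1, CAST 2 and CAST 1. Pluripotency genes (1 of 10 positive) had a median of −0.72 and an adjusted p of 0.0415, 0.505 with an estimated correlation. Their median was −1.13 without CAST 1, and their adjusted p was 0.103, 0.0575, 0.101 and 0.0836 without 129 3, hybrid 1, CAST 2 and CAST 3. Activity-regulated genes (6 of 20 positive) had a median of −0.54 and an adjusted p of 0.0415, 0.505 with an estimated correlation. Their adjusted p was 0.0724, 0.0765, 0.116 and 0.0836 without 129 1, 129 2, CAST 2 and CAST 3. Interferon response genes (10 of 22 positive) had a median of −0.15 and an adjusted p of 0.0415, 0.794 with an estimated correlation. Their adjusted p was 0.163, 0.0539 and 0.799 without 129 1, hybrid 1 and CAST 3, and their median ran from −0.52 without CAST 1 to 0.16 without 129 1, with −0.23, −0.49, −0.10 and −0.04 without 129 2, 129 3, CAST 2 and CAST 3. EdgeR called 0 members of the 4 lists over all genes, and 1 muscle gene and 1 interferon gene, both lower, adjusted over the list alone. At an unadjusted p under 0.05 the muscle, pluripotency, activity-regulated and interferon lists held 3, 3, 1 and 5 members, and DESeq2 called 2, 1, 0 and 2.

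Genes of spinal motor neuron identity did not pass in CAST against 129 as a list (6 of 18 positive, median −0.48, camera adjusted p = 0.187) and edgeR called 0 (1 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom). Mnx1, a motor neuron transcription factor, stood at 2.59 ± 0.805 CPM in CAST and 2.88 ± 2.05 CPM in 129 (log2 fold change −0.16 ± 0.74). Isl1, which acts with Lhx3 in motor neuron specification, stood at 39.2 ± 23.3 and 35.4 ± 25.2 CPM (0.15 ± 0.62). Chat, the enzyme of acetylcholine synthesis, stood at 8.77 ± 3.18 and 17.0 ± 11.3 CPM (−0.95 ± 0.56). The log2 fold change was −2.17 ± 1.19 for Lhx3, −2.60 ± 1.20 for Olig2, 1.26 ± 0.85 for Prph and −0.61 ± 0.46 for Ret. Gap43, a growth cone protein, had 0.62 ± 0.57, Inhba, which encodes an activin subunit, −1.91 ± 1.25, Atf3, a factor induced by axon injury, −0.50 ± 0.60, and Xist −0.78 ± 0.84 (SE). The edgeR adjusted p-values of these genes ran from 0.359 for Olig2 to 0.919 for Mnx1.

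The other lists did not pass camera in CAST against 129. Among lists of neural identity, the median log2 fold change and camera adjusted p were −0.33 and 0.332 for motor column factors, 0.49 and 0.433 for ventral progenitors (mean −0.04), −0.28 and 0.471 for spinal interneurons, and 0.23 and 0.240 for cranial and hindbrain neurons. Lmx1b is in both of the last lists (log2 fold change 3.14 ± 0.57, SE, edgeR adjusted p = 0.0412), and 3 hindbrain genes were higher adjusted over the list alone. The Lmx1b call ended without 129 1 (adjusted p = 0.168), 129 2 (0.178), hybrid 1 (0.0503), hybrid 2 (0.0568), hybrid 3 (0.0729), CAST 2 (0.144) and CAST 3 (0.0957). For markers of other cells the values were 0.46 and 0.711 for astrocytes, −1.09 and 0.0540 for endothelium, 1.58 and 0.0793 for microglia and blood, −0.53 and 0.471 for epithelium, −0.37 and 0.711 for neural crest (mean 0.04), and 0.24 and 0.422 for the cell cycle. For axon and synapse genes they were −0.36 and 0.0769 for regeneration-associated genes, −0.28 and 0.618 for receptors of myelin inhibition, 0.12 and 0.521 for the axonal cytoskeleton, −0.07 and 0.711 for synaptic vesicle release, and −0.45 and 0.0835 for ion channels. They were 0.12 and 0.931 for imprinted genes (mean −0.05), −0.59 and 0.0769 for Y-linked and X-inactivation genes, and 0.13 and 0.927 for class I antigen presentation. They were 0.60 and 0.471 for the integrated stress response, 0.08 and 0.830 for p53 targets, 0.01 and 0.927 for hypoxia and glycolysis (test direction down), 0.23 and 0.207 for cholesterol synthesis, and −0.50 and 0.346 for retinoic acid and hedgehog response. Adjusted over the list alone, 2 cell cycle and 2 cholesterol genes were higher and 2 imprinted genes lower. In the same count, 1 gene was higher in each of the interneuron, microglia, neural crest and ion channel lists, and 1 was higher and 1 lower in each of the astrocyte, myelin inhibition, hypoxia and retinoic acid lists. Over all lists together edgeR called 4 of 670 genes, Lmx1b, Igf2, mt-Nd5 and mt-Nd6, and DESeq2 called 53 and limma-voom 7.

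The largest single changes in CAST against 129 were mostly genes read in 1 line and nearly absent in the other. Reads of both lines were aligned to mm10, so a gene without counts in 1 line need not be unexpressed there. A sequence difference from the reference was not tested for these genes, and the bounds below compare counts only. Fbxo34 (ENSMUSG00000037536, chromosome 14, 47450421 to 47531962), an F-box protein gene, was at 20.9 ± 3.73 CPM in CAST and 0 in 129, at least 349-fold higher (edgeR adjusted p = 0.00750). Ramac (ENSMUSG00000038646, chromosome 7, 81762925 to 81769491), a cofactor of the mRNA cap methyltransferase, was at 57.2 ± 15.5 CPM in CAST and had 2 counts in 129, a ratio of 1416 (95% counting interval 392 to 11703, adjusted p = 0.00290). Tas1r1 (ENSMUSG00000028950, chromosome 4, 152027914 to 152038568), a taste receptor subunit, rose by 7.97 ± 0.72 log2 units (49.9 ± 5.16 CPM against 0.188 ± 0.176, adjusted p = 0.00321). Ifi202b (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744), an interferon-inducible gene, was at 16.1 ± 3.66 CPM in 129 and had 3 counts in CAST, a ratio of 223 (95% counting interval 76.0 to 1082, adjusted p = 0.00551). Hacd1 (ENSMUSG00000063275, chromosome 2, 13850282 to 14056135), an enzyme of very long chain fatty acid synthesis, fell by 7.04 ± 0.73 log2 units (0.160 ± 0.169 CPM against 24.9 ± 4.84, adjusted p = 0.00551). Plp2, Inafm1 and the microRNA gene Mir692-1 were at 0 counts in CAST and at least 362-fold, 145-fold and 2092-fold lower than in 129 (adjusted p = 0.00673, 0.00673 and 0.00654), and 18.4% of the exonic bases of Plp2 overlap an antisense gene. Mir6236 fell by 7.54 ± 0.45 log2 units (adjusted p = 0.00290).

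Igf2 (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816) had a log2 fold change of −5.91 ± 0.76 (SE, edgeR adjusted p = 0.00994; 0.0684 without CAST 2), and 62.8% of its exonic bases overlap another gene on its strand, so the gene of origin of its reads is uncertain. The rule also named Rasl2-9, Mfap1a, Aldh3a1, Cisd3, Lsm7, Rpl22l1 and Pin4, with log2 fold changes from 8.56 to 5.15, and Taf9, Usp26 and Rec8, which were lower. Of Taf9, 73.8% of exonic bases overlap another gene. Of the 23 called genes named here, 9 stayed past the threshold without each single library. Calls ended for 7, 13 and 11 genes without 129 1, 129 2 and 129 3, for 1, 1 and 3 without hybrid 1, hybrid 2 and hybrid 3, and for 1, 10 and 4 without CAST 1, CAST 2 and CAST 3, with a highest adjusted p of 0.187 (Rpl22l1 without 129 2).

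By chromosome, the median relative log2 fold change in CAST against 129 was 0.28 over 654 genes of chromosome 17 and −0.29 over 417 genes of chromosome 18 (camera adjusted p = 0.0340 for each; adjusted p = 0.491 and 0.600 with an estimated correlation). Genes of chromosome 18 stood at −0.43 relative to all libraries in CAST 1 and −0.50 in hybrid 2, and those of chromosome 17 at 0.28 in CAST 1. Over 521 genes of the X chromosome, the median was 0.38 in the hybrid against CAST (camera adjusted p = 0.00591; adjusted p = 0.981 with an estimated correlation) and −0.24 in CAST against 129 (adjusted p = 0.120), with CAST 1 at −0.44.

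The second comparison set the hybrid against 129. Hspb1 (ENSMUSG00000004951, chromosome 5, 135887919 to 135889563), a small heat shock protein and regeneration-associated gene, rose by 4.97 ± 0.84 log2 units (19.6 ± 20.5 CPM against 0.615 ± 0.143, edgeR adjusted p = 0.00685). Nkx6-2 (ENSMUSG00000041309, chromosome 7, 139579376 to 139582797), a homeodomain factor of ventral progenitors, rose by 2.76 ± 0.43 (28.1 ± 12.1 CPM against 4.14 ± 1.33, adjusted p = 0.00462), and 12.9% of its exonic bases overlap an antisense gene. Ddit3, a factor of the integrated stress response, was at 0 counts in the hybrid, at least 325-fold lower than in 129 (27.4 ± 5.52 CPM, adjusted p = 0.00262), and 6.13% of its exonic bases overlap a gene on its strand and 4.73% an antisense gene. Fdps, of the isoprenoid branch of cholesterol synthesis, rose by 7.50 ± 0.67 (149 ± 82.2 CPM against 0.812, adjusted p = 0.000383), and 26.7% of its exonic bases overlap another gene. These 4 genes belong to lists and were chosen after their values were seen. EdgeR called 1041 genes, 803 higher and 238 lower in the hybrid, with 3299 at an unadjusted p under 0.05. The libraries of the 2 lines did not overlap in any of these, and in 37.5% of all tested genes, where chance gives 10%. The count was 673, 522 and 564 without 129 1, 129 2 and 129 3, and 1717 without CAST 1.

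Calls in the hybrid comparisons lay mainly in genes whose exons overlap those of another gene. EdgeR called 13.4% of 5564 overlapping genes and 3.16% of the others in the hybrid against 129, 11.8% and 2.52% in the hybrid against CAST, and 0.809% and 0.981% in CAST against 129. Of the calls of this fit, 748 overlapping and 293 other genes were called against 129, and 657 and 234 against CAST. In a new fit with genes of overlapping exons left out, the hybrid count was 90 against 129 and 113 against CAST. The drop to these counts therefore includes calls lost among genes without an overlap.

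**Figure D4:**
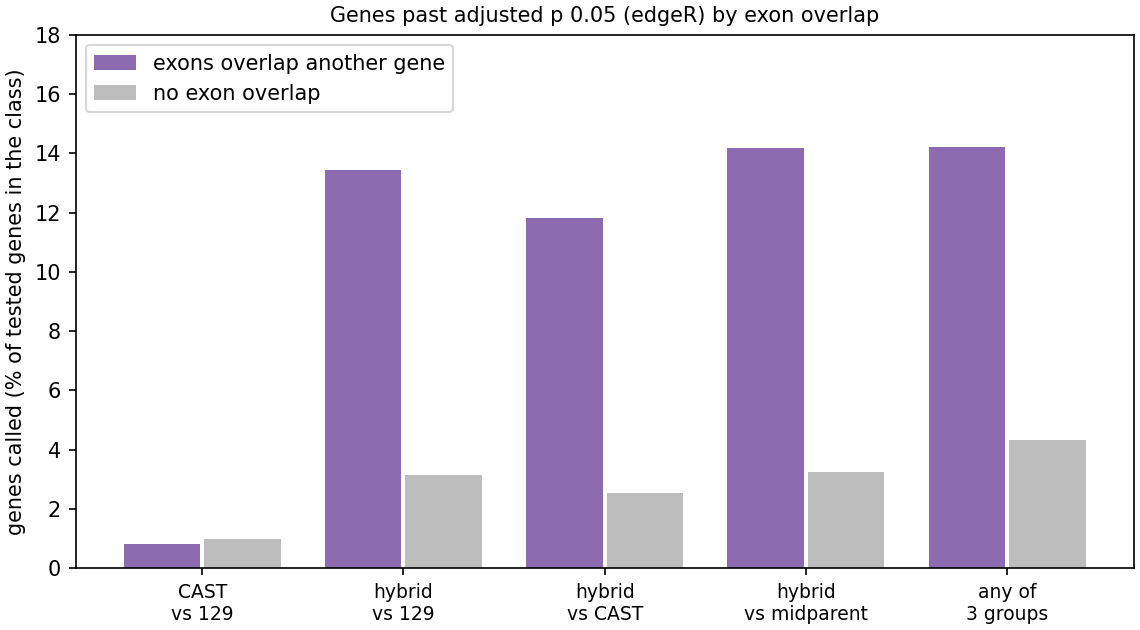
Percent of tested genes called by edgeR among genes whose exons overlap another gene and among the others, for the 5 tests; bars start at 0. In the hybrid against 129 the bars stand at 13.4% and 3.16%, and in CAST against 129 at 0.809% and 0.981%.

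The largest changes named by the rule in the hybrid against 129 involved such overlaps in most cases. Prn (ENSMUSG00000098754, chromosome 2, 131909957 to 131956130) was at 199 ± 96.1 CPM in the hybrid and 0 in 129, at least 3695-fold higher (adjusted p = 0.00133), and 96.9% of its exonic bases overlap Prnp on the same strand. Eif3j2, Entpd4 and Cd72 were at least 1877-fold, 1097-fold and 770.4-fold higher (adjusted p = 0.000240, 0.000648 and 0.000657), with 3.11%, 30.4% and 41.6% of exonic bases in an overlap. Tmem254c (ENSMUSG00000072680, chromosome 14, 26063919 to 26067355), which has no overlapping exon, was at 31.3 ± 11 CPM and at least 506-fold higher (adjusted p = 0.00186). Myadm (ENSMUSG00000068566, chromosome 7, 3289080 to 3300442), which encodes a myeloid-associated membrane protein, was at 0 in the hybrid, 489 ± 138 CPM in 129 and 282 ± 33.9 CPM in CAST, at least 5794-fold lower than in 129 (adjusted p = 0.000240), and 5.27% of its exonic bases overlap another gene on its strand. Mir692-1, Mir6236, mt-Nd5 and Tbc1d22b were also at 0 counts in the hybrid, at least 1797-fold, 1411-fold, 1334-fold and 948-fold lower than in 129, and 0.77% of the exonic bases of mt-Nd5 overlap an antisense gene. The 10 genes stayed past the threshold without each single library.

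Among lists in the hybrid against 129, camera called 9 and edgeR 21 of 670 list genes over all genes, with DESeq2 at 74 and limma-voom at 22. Cell adhesion genes (1 of 29 positive, median −1.13, camera adjusted p = 0.00554) and extracellular matrix genes (1 of 27 positive, median −1.02, adjusted p = 0.00554) were lower as groups, both with adjusted p = 0.706 with an estimated correlation. Their medians were −1.91 and −2.54 without hybrid 1, and −0.66 and −0.58 without hybrid 2. Hybrid 1 stood at 6.44 and 7.09 log2 CPM in these lists, hybrid 2 at 4.6 and 4.66, and hybrid 3 at 5.36 and 4.75. Ion channel genes (4 of 31 positive, median −1.08, adjusted p = 0.00684), TGF-beta signalling genes (4 of 27, −0.86, 0.0141), axon guidance genes (10 of 41, −0.97, 0.0145), interferon genes (4 of 22, −0.59, 0.0306), regeneration-associated genes (7 of 30, −0.52, 0.0499) and synaptic vesicle genes (5 of 24, −0.65, 0.0499) were also lower. Respiratory chain genes were positive in 26 of 27 members (median 1.07, camera adjusted p = 0.0306). All 7 of these had adjusted p = 0.706 with an estimated correlation. EdgeR called 0 members of the adhesion, extracellular matrix, ion channel, TGF-beta, axon guidance, synaptic vesicle and respiratory lists over all genes and 0 adjusted over the list alone (3, 3, 4, 1, 7, 3 and 6 at an unadjusted p under 0.05; 1, 1, 2, 1, 2, 2 and 4 by DESeq2). In the interferon list it called 1 member, Isg15, lower, and 3 lower adjusted over the list alone. The Isg15 call ended without 129 1 (adjusted p = 0.1003), 129 2 (0.0987), 129 3 (0.0866), hybrid 1 (0.0668), hybrid 2 (0.0993), hybrid 3 (0.106) and CAST 2 (0.0529). In the regeneration list it called 1 member, Hspb1, higher, both over all genes and adjusted over the list alone.

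With the exon length offset, chosen after seeing the data, the calls of ion channel, axon guidance, synaptic vesicle and respiratory chain genes ended (camera adjusted p = 0.255, 0.111, 0.125 and 0.125; over the alternatives these ran from 0.000686, 0.00334, 0.00500 and 0.00132 to 0.706, the value with an estimated correlation). With no scaling beyond library size those of regeneration-associated and synaptic vesicle genes ended (0.0512 and 0.0544; over the alternatives from 0.0117 and 0.00500 to 0.706), and that of synaptic vesicle genes also without both CAST 1 and hybrid 2 (0.0532). Fry called none of the 9 lists (adjusted p = 0.0504 to 0.420). Most of the 9 list calls also ended without at least 1 library. The camera adjusted p of ion channel genes was 0.0577 without 129 3 (median −0.66). That of TGF-beta genes was 0.0506 without hybrid 3, with medians of −1.58 and −0.55 without hybrid 1 and hybrid 2, and that of axon guidance genes was 0.0998 without hybrid 2. For interferon genes it was 0.0964, 0.127 and 0.0506 without 129 1, hybrid 1 and hybrid 3, with a median of −0.94 without hybrid 2. For respiratory chain genes it was 0.254 without hybrid 2, where the median was 0.51, and 0.0506 without hybrid 3. For regeneration-associated genes it was 0.0579, 0.0681, 0.0776 and 0.0866 without 129 2, 129 3, hybrid 1 and hybrid 3. For synaptic vesicle genes it was 0.254, 0.174 and 0.118 without 129 3, hybrid 1 and hybrid 2, with medians of −0.34 and −0.38 without 129 3 and hybrid 2. Hybrid 2 stood at 8.63 log2 CPM in the respiratory list, where the other hybrid libraries stood at 6.73 and 7.59.

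Lists that did not pass in the hybrid against 129 included motor neuron identity (median −0.73, camera adjusted p = 0.108) and the posterior Hox genes (−0.74, 0.108). Among imprinted genes (median −0.16, adjusted p = 0.490) 2 were called higher and 2 lower, and 5 higher and 3 lower adjusted over the list alone. Igf2 was among the lower ones, at 67.5 ± 37.6 CPM in the hybrid. Oligodendrocyte genes had a median of −1.39 and a mean of −0.07 (adjusted p = 0.455), with 2 members higher and 4 lower at an unadjusted p under 0.05. Fry called the microglia and blood list up (adjusted p = 0.00553), which camera did not call with either correlation. EdgeR called 1 of its 3 members, Cx3cr1, the fractalkine receptor, at 28.7 ± 8.47 CPM in the hybrid and with 3 counts in 129. Fry also called the mitochondrially encoded list down (adjusted p = 0.00118), which camera did not call either. Its median was 0.00, but its 3 members did not move alike. The value at the bound, −2.80, leaves out mt-Nd6, at the floor in both lines, and lies between the opposite bounds of mt-Nd5 and mt-Cytb. EdgeR called mt-Nd5 lower and mt-Cytb higher (57 counts against 0 in 129, at least 27.6-fold, adjusted p = 0.0145), and the mt-Cytb call ended without 129 2 (adjusted p = 0.0583), 129 3 (0.0551) and hybrid 3 (0.0582). Of 35 called genes followed in this comparison, 18 stayed past the threshold without each single library. Calls ended for 13, 16 and 14 genes without 129 1 to 3, for 8, 13 and 15 without hybrid 1 to 3, and for 0, 4 and 2 without CAST 1 to 3.

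The hybrid was also set against CAST. Scn3b (ENSMUSG00000049281, chromosome 9, 40269217 to 40291618), a sodium channel subunit, fell by 3.02 ± 0.51 log2 units (14.2 ± 6.51 CPM against 116 ± 46.6, edgeR adjusted p = 0.00650). Hspb1 rose by 5.46 ± 0.87 (adjusted p = 0.00523), Fdps rose by 5.18 ± 0.60 (adjusted p = 0.00118), and Ddit3, whose exons overlap other genes (6.13% of bases on its strand, 4.73% antisense), was at least 553-fold lower (adjusted p = 0.00193). These 4 list genes were chosen after their values were seen. Of genes named by the rule, mt-Nd5 was at 0 in the hybrid and at least 15266-fold lower than in CAST (adjusted p = 0.000236), with 0.77% of its exonic bases in an antisense overlap. The limit given above on the counting of mitochondrial reads holds here as well. Myadm, Akr1b3, Tbc1d22b and Pgam5 were at least 3415-fold, 1099-fold, 770-fold and 745-fold lower, with 58.1% of the exonic bases of Pgam5 and 7.73% of those of Tbc1d22b in an antisense overlap, and 4.66% of those of Tbc1d22b in a same-strand overlap. Akr1b3 (ENSMUSG00000001642, chromosome 6, 34302434 to 34317478), aldose reductase, has no overlapping exon and was at 107 ± 84.5 CPM in CAST and 0 in the hybrid. Prn, Entpd4, Plp2, Sla2 and Tmem254c were at least 2957-fold, 878-fold, 781-fold, 537-fold and 405-fold higher, and 23.6% of the exonic bases of Sla2 overlap an antisense gene. EdgeR called 891 genes, 654 higher and 237 lower, with 2349 at an unadjusted p under 0.05. The libraries of the 2 lines did not overlap in any of these, and in 19.2% of all tested genes, where chance gives 10%.

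Camera called 0 of the 38 lists in the hybrid against CAST (9 at an unadjusted p under 0.05, lowest adjusted p = 0.0981), and fry called 1. That list was the mitochondrially encoded genes (fry adjusted p = 2.53e-06, median −10.09, −6.96 at the bound), of which edgeR called mt-Nd5 and mt-Nd6 lower and mt-Cytb higher (57 counts against 0, at least 22.1-fold, adjusted p = 0.0184). The mt-Cytb call ended without hybrid 1 (adjusted p = 0.0602), hybrid 3 (0.0645), CAST 2 (0.0609) and CAST 3 (0.0569). Camera called 3 lists without both CAST 1 and hybrid 2, and 7, 4 and 1 without hybrid 3, CAST 1 and CAST 2. The lowest camera value belonged to the oligodendrocyte lineage (median 1.27), where edgeR called 2 members higher, and 5 higher and 1 lower adjusted over the list alone. The posterior Hox list had a positive value in 12 of 13 members (median 0.90, adjusted p = 0.109). Of 27 called genes followed in this comparison, 15 stayed past the threshold without each single library. Calls ended for 3, 3 and 2 genes without 129 1 to 3, for 7, 4 and 8 without hybrid 1 to 3, and for 1, 8 and 5 without CAST 1 to 3.

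The last comparison asked whether the hybrid departed from the mean of both parental lines. Slc7a11 (ENSMUSG00000027737, chromosome 3, 49892526 to 50443614), the cystine transporter, rose by 6.27 ± 0.89 log2 units (536 ± 269 CPM in the hybrid, 7.19 ± 3.05 in 129 and 6.63 ± 6.61 in CAST, edgeR adjusted p = 0.00169). Hspb1 rose by 5.22 ± 0.64 (adjusted p = 0.000797) and Nkx6-2 by 2.01 ± 0.34 (adjusted p = 0.00443). Gpr17 and Mog, of oligodendrocyte precursors and myelin, were higher against the midparent (adjusted p = 0.00458 and 0.00443), at 3.61 ± 2.67 and 13.7 ± 8.47 CPM against at most 0.0875 and 0.185 CPM in the parental lines, but their list of 12 did not pass (median 0.41, camera adjusted p = 0.558), with 4 members higher and 2 lower at an unadjusted p under 0.05. Against 129 the Gpr17 call ended without 129 1 (adjusted p = 0.101), 129 2 (0.107), 129 3 (0.0621), hybrid 1 (0.0501) and hybrid 2 (0.0506), and the Mog call without 129 2 (0.110), 129 3 (0.104), hybrid 1 (0.0505), hybrid 2 (0.0506) and hybrid 3 (0.0914). Against CAST the Gpr17 call ended without 129 1 (0.0535), hybrid 1 (0.0701), hybrid 2 (0.0592), CAST 2 (0.129) and CAST 3 (0.110), and the Mog call without CAST 2 (0.0512). Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), the intermediate filament of astrocytes, rose by 3.90 ± 0.86 (181 ± 116 CPM against 11.1 ± 13.8 and 13.2 ± 10.5, adjusted p = 0.0211). The Gfap call ended without 129 3 (adjusted p = 0.0517), hybrid 2 (0.0974) and CAST 3 (0.0535). These 6 list genes were chosen after their values were seen. EdgeR called 1089 genes, 873 higher and 216 lower, with 2733 at an unadjusted p under 0.05. The count was 1850 without CAST 1, and 153 in a new fit with genes of overlapping exons left out. The main fit called 301 genes without such an overlap.

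Genes named by the rule in the midparent comparison were Prn, Entpd4, Eif3j2, Tmem254c and Cd72, which were higher, and mt-Nd5, Myadm, Akr1b3, Tbc1d22b and Pgam5, which were at 0 counts in the hybrid. Eif3j2 (ENSMUSG00000043424, chromosome 18, 43475418 to 43477796), a copy of an initiation factor subunit gene, was at 107 ± 13 CPM in the hybrid, 0 in 129 and 0.0187 CPM in CAST. Camera called ion channel genes (2 of 31 positive, median −0.74) and cell adhesion genes (3 of 29 positive, median −0.51), each with an adjusted p of 0.0343, and adjusted p = 0.790 with an estimated correlation. EdgeR called 1 ion channel gene, Scn3b, lower over all genes and 0 adjusted over the list alone. The Scn3b call ended without 129 2 (adjusted p = 0.0562), 129 3 (0.0614), hybrid 1 (0.0840), hybrid 2 (0.107), CAST 2 (0.0529) and CAST 3 (0.0535). It called 0 adhesion genes in either count (4 lower at an unadjusted p under 0.05, 1 by DESeq2). With the exon length offset, chosen after seeing the data, both list calls ended (adjusted p = 0.198 for ion channel and 0.0920 for adhesion genes; over the alternatives from 0.000295 to 0.790 for each). The adjusted p of ion channel genes was 0.0900, 0.182, 0.0718 and 0.0646 without 129 3, hybrid 2, CAST 2 and CAST 3. That of adhesion genes was 0.0660, 0.193, 0.0718 and 0.0848 without the same 4 libraries, and their median was −1.44 without hybrid 1. Of 30 called genes followed in this comparison, 20 stayed past the threshold without each single library. Calls ended for 4, 6 and 5 genes without 129 1 to 3, for 4, 10 and 8 without hybrid 1 to 3, and for 0, 4 and 6 without CAST 1 to 3. Across the 3 groups together, the joint test called 1192 genes, with 3135 at an unadjusted p under 0.05 and 788 without 129 2.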

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

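Tests that left out CAST 1 and hybrid 2, genes at the floor in a group or genes with overlapping exons, that summed overlapping genes, used an exon length offset or weighted the libraries were chosen after seeing the data. With DESeq2 the counts were 939 in CAST against 129 (main value 136), 2100 in the hybrid against 129 (1041), 1597 in the hybrid against CAST (891), 1790 against the midparent (1089) and 2506 in the joint test (1192). In the simulated counts DESeq2 made 29 false calls in CAST against 129 where edgeR made 4. Those counts lacked the structure of the real libraries, so they do not show how many of the 939 or 136 calls are false. Limma-voom called 234 in CAST against 129. Limma-voom with library weights, which ran from 0.108 for CAST 1 to 11.1 for 129 2, called 5139, 8231, 3870, 6453 and 9649 in the 5 tests, and the cause was not tested. The replicate block left 6, 561, 526 and 651 in CAST against 129, the hybrid against 129, the hybrid against CAST and the joint test, with fewer residual degrees of freedom. A threshold of 0.01 left 32, 506, 484 and 639 in the same 4 tests.

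Without CAST 1 and hybrid 2, 230 genes were called in CAST against 129, with the exon length offset 259, and with both 263, and the cause was not tested. Without genes at the floor in a group the 5 counts were 52, 288, 227, 370 and 376, where 704 genes were no longer tested. Without genes whose exons overlap another gene, 90, 113, 153 and 221 were called in the hybrid against 129, against CAST, against the midparent and in the joint test, and 73, 115, 115 and 207 when CAST 1 and hybrid 2 were left out as well. The main fit called 293, 234, 301 and 402 genes without an exon overlap in these 4 tests, so the new fits also lost calls among such genes. Of the 90 genes, 52 were higher in the hybrid, and of the 113 genes 60, so that the excess of higher genes was smaller in these new fits. With overlapping genes summed into 23949 loci, the same 4 counts were 263, 241, 317 and 415.

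Leaving out each library in turn gave 26 to 157 genes in CAST against 129, 522 to 1717 in the hybrid against 129, 643 to 923 in the hybrid against CAST, 884 to 1850 against the midparent and 788 to 1485 in the joint test. The lowest counts came without 129 2 in CAST against 129, the hybrid against 129 and the joint test, and the highest without CAST 1 in the hybrid against 129, against the midparent and in the joint test, and the cause was not tested. For list tests the ranges were 11 to 17, 5 to 13, 0 to 7 and 0 to 7 lists in CAST against 129, the hybrid against 129, the hybrid against CAST and the midparent.

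Camera called 13, 9, 0 and 2 lists in these 4 comparisons. With an estimated correlation it called 0 lists in all 4 (2, 1, 1 and 0 at an unadjusted p under 0.05), and fry called 1, 2, 1 and 2. Without CAST 1 and hybrid 2 camera called 15 in the hybrid against 129 and 3 in the hybrid against CAST. Against the midparent it called 0 with the exon length offset and 4 without genes at the floor. The medians of chromosome 18 ran from −0.40 to −0.19 in CAST against 129 and from −0.49 to −0.23 in the hybrid against 129 when each library was left out, and that of the X chromosome from 0.26 to 0.49 in the hybrid against CAST.

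Of 188 log2 fold changes of single genes, 115 were past the threshold, 54 of these under every alternative run for them and 61 not under at least 1, and 0 past the threshold reversed. This count did not include the fits that left out or summed overlapping genes, left out genes at the floor or weighted libraries. It also left out limma-voom, upper quartile scaling, other filters, no robust estimation and the 2 compared groups alone. The 54 calls were therefore not tested against exon overlap. The replicate block ended 52 calls, the exon length offset 14, no scaling 8, leaving out CAST 1 and hybrid 2 ended 9, and DESeq2 ended 1 and added 3. Depth differed between libraries, and genes under about 3 counts in a group give only bounds. An alternative that would have added 2 further CAST samples was not run.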

Other observations

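The motile cilia list and its tests, and the tests of overlapping genes and of the share of Hox-expressing cells, were chosen after the result was seen. Genes of motile cilia, the machinery of ependymal and other multiciliated cells, were called higher in the hybrid than in each parental line by camera with a preset correlation, but not with an estimated one (adjusted p = 0.704 against 129 and 0.942 against CAST), and fry called them in no comparison (0.0948 against 129, 0.228 against CAST and 0.0835 against the midparent). Camera also called the list higher in CAST than in 129 (median 0.79, 50 of 65 positive, adjusted p = 0.0420; adjusted p = 0.847 with an estimated correlation), where edgeR called 0 members (11 at an unadjusted p under 0.05, 2 by DESeq2). Among 38 members whose exons overlap no other gene it called the hybrid against 129 (adjusted p = 6.73e-09) and CAST (3.31e-07) but not CAST against 129 (0.0814), and none with an estimated correlation (0.704, 0.942 and 0.847). Of 77 genes written down, 65 were tested, of which 20 had every hybrid library above every parental one and 62 had a positive log2 fold change in the hybrid against 129 (median 2.15, camera adjusted p = 6.51e-13; adjusted p = 0.704 with an estimated correlation). EdgeR called 5 higher over all genes, and 38 higher and 1 lower adjusted over the list alone. The lower member, Ccno, was at 0 CPM in the hybrid, 0.470 ± 0.313 in 129 and 2.13 ± 2.46 in CAST. It was not called over all genes (edgeR adjusted p = 0.157 against 129 and 0.0537 against CAST). Dnaic1, a dynein intermediate chain, was at 14.4 ± 2.87 CPM in the hybrid and 0.859 in 129 (log2 fold change 4.05 ± 0.52, adjusted p = 0.00175), though its exons overlap another gene. Drc1, of the axonemal dynein regulatory complex, was at 44.9 ± 12.8 CPM in the hybrid, 8.45 ± 2.65 in 129 and 14.4 ± 11.2 in CAST (2.41 ± 0.55 against 129, adjusted p = 0.0302), a call that ended without 129 1 (adjusted p = 0.0656), 129 2 (0.149), 129 3 (0.138), hybrid 2 (0.0723) and hybrid 3 (0.0924).

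In the hybrid against CAST the cilia median was 1.41 with 61 of 65 positive (camera adjusted p = 1.09e-10; adjusted p = 0.942 with an estimated correlation), and edgeR called 2 members higher over all genes, and 7 higher and 1 lower adjusted over the list alone. Against the midparent it was 1.75, with 13 members called and 36 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.63e-14; adjusted p = 0.786 with an estimated correlation). The list mean was 3.18 ± 0.26 log2 CPM in the hybrid, 1.16 ± 0.42 in 129 and 1.56 ± 1.14 in CAST (SD, n = 3), where CAST 2 alone was at 2.82. Among the 38 members with no overlap the median against 129 was 2.25, with 3 called and 25 higher and 1 lower adjusted over the list alone, and against CAST edgeR called 0 of these (5 higher and 1 lower adjusted over the list alone, 15 higher and 1 lower at an unadjusted p under 0.05, 10 called by DESeq2 and 4 by limma-voom). Foxj1, a regulator of motile ciliogenesis, stood at 103 ± 43.3 CPM in the hybrid, 33.3 ± 29.5 in 129 and 56.8 ± 45.5 in CAST and was not called (adjusted p = 0.271 against 129).

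Calls in the hybrid comparisons concentrated in genes with overlapping exons, where the percent called against the midparent was 4.36 times that of other genes (14.2% and 3.25%) and in CAST against 129 0.824 times. A sequence difference from the reference is argued against for 32 genes at the floor in the hybrid and at 5 CPM or more in both parental groups. The hybrid carries the genomes of both. Of the 32 genes 23 have overlapping exons, while 788 overlapping genes were called against the midparent. The 32 genes were chosen for reads in both parental lines, so they cannot weigh a sequence difference as a cause of the other calls. The lowest expected count of the 32 genes in a hybrid library was 36.7, so lower depth does not account for their floor. That value was fixed by the choice of genes at 5 CPM or more. It cannot weigh depth as a cause of the concentration of calls in overlapping genes. The hybrid was higher at 14 of the 15 tested overlapping partners of the 32 genes, but also at 84.1% of 577 partners under 5 CPM of all genes at 5 CPM or more. The part of the test that asked for 80% of partners therefore adds little. In the reverse class, 148 genes at 5 CPM or more in the hybrid and at the floor in both parental lines, an exchange of reads would leave partners lower, yet of 182 partners 110 were lower and 72 higher (14 called lower and 21 higher), so a clean exchange is not shown. A candidate explanation is that reads at overlapping genes were credited to genes by another rule or gene model in the hybrid libraries, a hypothesis found and tested on the same data, and a difference between the lines stays open and was not tested.

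Short transcripts were higher and long transcripts lower in CAST 1 and hybrid 2, where, of 5 length classes of equal size, the shortest stood at 1.03 in both and the longest at −1.23 and −0.90 in relative log2 expression. Random loss of reads alone would not give these slopes, since thinning the deepest library of each group changed its slope by at most 0.00253. Thinning at 1 rate for all genes keeps the expected share of each gene, so this outcome was fixed in advance. It cannot weigh other ways in which libraries with fewer reads differ. The median slope within lists was at least 0.963 times that over all genes. Single lists ran from −1.94 to −0.14 in CAST 1 and from −1.26 to 0.76 in hybrid 2. Many lists hold genes of several cell types, so these values cannot weigh a different mix of cells as a cause. Within 89.3% of 28 lists the slope was negative in both libraries, which is consistent with fewer long transcripts recovered in them.

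The posterior Hox genes had a median log2 fold change of −2.04 in CAST against 129 (median absolute deviation 2.07, range −2.70 without CAST 3 to −1.41 without 129 1), which camera called with a preset correlation (adjusted p = 4.6e-05) but not with an estimated one (adjusted p = 0.586), while edgeR and limma-voom called 0 of 13 members (7 at an unadjusted p under 0.05, 4 by DESeq2). The transcript length trend is argued against, since the median was −2.18 without CAST 1 and hybrid 2 and with the exon length offset. A loss of all Hox-expressing cells alike is argued against, since anterior Hox genes had a median 2.54 above that of posterior ones. A lower share of trunk-level cells alone would give the same pattern, and the test cannot weigh it. A difference between the lines stays open and was not tested.

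Other splits of the libraries were counted for each test. For CAST against 129 the real split gave 136 genes, as the 1 of 10 splits with so many, and the highest other split gave 0. For the hybrid against 129 it gave 1041, also 1 of 10, with 0 in the highest other. For the hybrid against CAST 2 of 10 splits gave at least 891, and the highest other, hybrid 1, CAST 2 and CAST 3 against hybrid 2, hybrid 3 and CAST 1, gave 3831. These 10 splits are too few for a share under 0.05. Against the midparent 3 of 100 drawn splits (840 possible) gave at least 1089, with a highest other value of 5240. In the joint test 3 of 86 (280 possible) gave at least 1192, with a highest other of 3291. Both shares are under 0.05, but other splits gave far higher counts than the real one. The libraries therefore cannot be treated as interchangeable, and no conclusion on chance is drawn from these 2 tests. The splits with several times the real count put hybrid 2, hybrid 3 and CAST 1 together, the libraries with negative length slopes, which points to a structure of the samples besides the lines.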
